A study of Mus musculus with 10 samples.

How the data were processed

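Total RNA from cultured mouse tumour cells was made into messenger RNA libraries with a standard kit and sequenced from both ends on an Illumina HiSeq instrument, per the labels. The deposited table holds 1 raw count per gene and library for 10 libraries, and the values were whole numbers with totals that differed between libraries. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.0.5, HTSeq, featureCounts and DESeq2 with the mouse build GRCm39. The notes do not give the order of these tools, the annotation release, the strand setting or how reads with several matches were handled. The table has 60676 genes and loci, of which 57180 have Ensembl identifiers and 3496 are loci named XLOC. Symbols were matched by Ensembl identifier to a reference annotation for 51884 of them, and no coordinates are printed because positions were not given in the table. All columns were used.

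Libraries were grouped by the line, the knockdown and the re-expressed form named in the titles, giving 5 groups of 2. The meaning of c30 and ect beyond a mutant form of Sdc1 is not given in the sources used here. Total counts ranged from 11349447 to 15041133, so that the floor for a count of 0, taken as 3 counts per library, lay between 0.199 and 0.264 CPM (counts per 1000000 counts of the library). Intervals at the 95% level are exact Poisson intervals. Intervals and floors cover counting error only.

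Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, robust dispersion estimates, and the quasi-likelihood test, 2-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and genes were called at an adjusted p under 0.05. The 3 MC38 comparisons shared 1 fit of 6 libraries, the B16 comparison used the 4 B16 libraries, and the comparison of the knockdown groups of both lines used all 10. The common biological coefficient of variation was 4.84% in MC38, 8.68% in B16 and 6.65% over all 10 libraries. Standard errors of log2 fold changes are from the fitted model, and group means with their SD over 2 libraries are CPM of the TMM-normalized library sizes of that fit, so that a mean differs slightly between fits. Values for single libraries, marker sums and the levels of genes at 0 in a line are CPM of the library total, except those of Rps27a, which are CPM of TMM-normalized library sizes.

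The comparisons, the tests, the 31 gene lists and the alternatives planned were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry (limma 3.58.1). Named genes followed a rule: Sdc1, then the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM and no overlap between the libraries of both groups, without predicted genes, pseudogenes or loci with no symbol. The rule then took up to 2 called members per list with the smallest adjusted p, or 3 for the 5 interferon and antigen presentation lists. The comparison of the lines took the 5 largest changes each way, and a comparison with few calls took the 5 smallest p-values each way. Members of a list could be named where a list or gene did not pass. Some genes that this rule takes are not reported.

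The alternatives planned were another size factor method (RLE), no filter on low counts, a filter at 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, replicate number as a block, leaving out each library, a fold change of at least 2, all 10 libraries in 1 fit and only the 4 libraries compared. Chosen after seeing the data were a fit without unnamed loci, mitochondrially encoded and ribosomal protein genes, a correction for transcript length and GC content (mgcv 1.9.3), list tests without single libraries, and the test of the difference between the effects in B16 and MC38. Overlap between comparisons that share the knockdown libraries was set against 40 simulations of groups with no effect. Splitting groups of 2 by chance could not be tested.

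The tests were tried on simulated counts with 200 changed genes, drawn from the means and library sizes of the real libraries. At changes of 1.5-fold, the edgeR test recovered 64% in the c30 comparison, 76% in the ect comparison, 64% in c30 against ect, 52% in B16 and 54% between lines. At 1.2-fold it recovered 24%, 18%, 18%, 10% and 12%, and at 2-fold 78%, 78%, 78%, 72% and 84%. False calls numbered 7, 11, 10, 16 and 13. Each gene was drawn on its own, so a trend over many genes of a library was not simulated. B16 wild-type replicate 2 had such a trend, so recovery with the real B16 libraries may be lower. Camera called 3 of 3 raised sets and 0 unchanged sets. These sets held random genes drawn independently, so calls caused by correlation between the genes of a list were not tried. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.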

Results

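Transcript levels were measured by RNA sequencing in 2 mouse tumour lines, MC38, a colon adenocarcinoma line, and B16, a melanoma line. All 10 libraries came from cells in which syndecan-1 had been knocked down and which had been given interferon gamma (IFNγ) at 10 ng/ml for 24 h. Syndecan-1, the product of Sdc1, is a transmembrane proteoglycan that carries heparan sulphate chains. In MC38 there were 3 groups of 2 libraries. They were the knockdown alone, the knockdown with a form of Sdc1 that the labels call c30, and the knockdown with a form called ect. In B16 there were 2 groups of 2 libraries, the knockdown alone and the knockdown with wild-type Sdc1 put back. The labels call c30 and ect mutants and do not describe them further. No library without the knockdown, without IFNγ or with an empty vector is analysed here, so each re-expression group is set against the knockdown of its own line. Total counts per library ranged from 11349447 to 15041133. A single Ensembl row without a symbol took between 0.621% and 2.42% of the counts of a library. Pigment and melanocyte markers summed to 23300 to 24600 CPM (counts per 1000000 counts of the library) in the B16 libraries and 305 to 434 CPM in the MC38 libraries, where c30 replicate 2 held 28 counts of Dct and 31 of Tyrp1 against at most 7 of either in any other MC38 library. Leukocyte markers summed to 10.6 to 15.3 CPM in all 10. Of 21 epithelial markers, 3 or 4 reached 1 CPM in each MC38 library and 3 in each B16 library. Of 14 mesenchymal transition genes, 13 did so in each MC38 library and 5 in each B16 library. Values per library of Sdc1 and marker genes are scaled to the library total, and group means of tested genes to TMM-normalized library sizes. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

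Sdc1 (ENSMUSG00000020592.16) was measured in every library before any other comparison. In MC38 the knockdown libraries held 337 and 398 Sdc1 counts, or 24.5 and 30 CPM. The c30 libraries held 1101 and 1143 counts, or 97.0 and 99.5 CPM. The ect libraries held 255 and 379 counts, or 22.4 and 25.2 CPM, a range that overlapped that of the knockdown. In B16 the knockdown libraries held 533 and 495 counts (40.7 and 43.1 CPM) and the wild-type libraries 898 and 713 counts (71.1 and 56.9 CPM). The rise with c30 was 1.86 on the log2 scale (standard error (SE) 0.087, edgeR adjusted p = 6.18e-31), a 3.62-fold higher level. The ect libraries did not differ from the knockdown by the same test (log2 fold change -0.17, SE 0.10, edgeR adjusted p = 0.325). The difference in B16 was 0.64 (SE 0.12) and did not pass the edgeR test (adjusted p = 0.269), although both wild-type libraries lay above both knockdown libraries. At about the same fold it passed with DESeq2 (adjusted p = 0.0224), with replicate number as a block (0.0112), with all 10 libraries in one edgeR fit (0.0069) and with a correction for transcript length and GC content (0.00555), and did not with limma-voom (0.309). Without wild-type replicate 1 the edgeR log2 fold change was 0.48 (adjusted p = 0.000834) and without wild-type replicate 2 it was 0.78 (1.1e-10). A count per gene does not separate transcripts of the cell's own Sdc1 from those of a re-expressed form, and transcripts of a form that lacks or alters part of the sequence can be counted less completely.

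**Figure D1:**
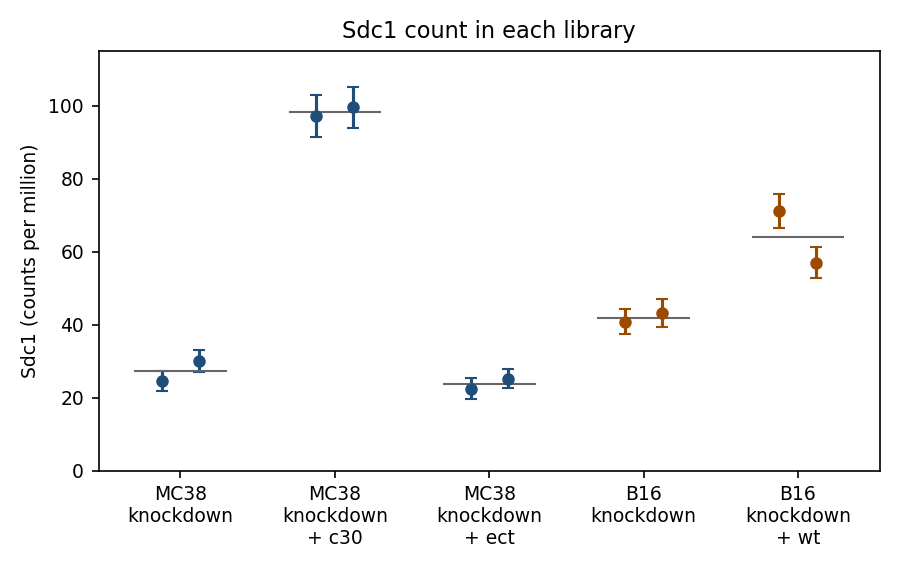
Sdc1 level in each of the 10 libraries, in CPM (vertical axis, from 0), by group (horizontal axis). Points are single libraries, bars the 95% exact Poisson interval of the count, which covers counting error only, and horizontal lines the mean of the 2 libraries; the c30 libraries sit at 97.0 and 99.5 CPM and the ect libraries at 22.4 and 25.2 CPM, beside 24.5 and 30 CPM in the MC38 knockdown.

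The comparison of c30 with the knockdown in MC38 asked which IFNγ-treated transcripts differed once c30 was present. Antiviral genes, interferon-induced GTPases, cholesterol synthesis genes and hypoxia and glycolysis genes were lower with c30 as lists, also with an estimated correlation. Collagen genes were lower and ribosomal protein genes higher by camera with its preset correlation only (adjusted p = 0.217 for both with an estimated correlation). Of 15031 genes tested, 1165 passed (496 higher and 669 lower, edgeR adjusted p under 0.05). Their median absolute log2 fold change was 0.30, and 25 of the higher and 35 of the lower genes differed at least 2-fold. Apart from Sdc1, the largest rises among genes with at least 5 CPM were in Tnc, which encodes the matrix protein tenascin-C (log2 fold change 1.14, SE 0.17), Rps10 (1.03, SE 0.17), Rab26os (0.93, SE 0.22) and Mir17hg, the host transcript of a microRNA cluster (0.93, SE 0.16). Enpp5 (0.87, SE 0.25) and Glrx, which encodes glutaredoxin (0.85, SE 0.17), followed. Tmem171, Plagl1 and Efcab5 rose by 0.78 to 0.82. The largest falls among genes with at least 5 CPM were in Ifit3, an antiviral interferon-induced gene (-1.39, SE 0.20), C1s1, a complement protease (-1.21, SE 0.22), and Sned1 (-1.16, SE 0.22). They were followed by Prelp (-1.15, SE 0.20), Serpinb1a (-1.13, SE 0.23) and Cd74, the invariant chain of MHC class II (-1.03, SE 0.18). Slurp1, Aldh3a1, Pmaip1 and Fam43a fell by 0.93 to 1.02.

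Of the interferon lists in the c30 comparison, 14 of the 30 tested antiviral interferon-stimulated genes were lower and 0 higher (18 lower adjusted over the list alone). Oas3 had a log2 fold change of -0.71 (SE 0.11) and Oasl2 of -0.53 (SE 0.10), both of which encode oligoadenylate synthetase family proteins. Among the guanylate-binding proteins and immunity-related GTPases, families that act against intracellular pathogens, 12 of 17 were lower and 0 higher (13 lower adjusted over the list alone). Iigp1 went from 608 ± 16.6 CPM to 442 ± 9.08 CPM (SD, n = 2 per group; log2 fold change -0.46, SE 0.04, edgeR adjusted p = 2.26e-14). Igtp had -0.42 (SE 0.04) and Tgtp1 -0.30 (SE 0.04). Both lists passed camera, a test of a list against all other genes (adjusted p = 7.54e-14 and 1.55e-13), and also with an estimated correlation (adjusted p = 0.0364 for both). For MHC class I presentation, 6 of 21 genes were lower (11 adjusted over the list alone). H2-T23 had -0.47 (SE 0.08), the peptide transporter gene Tap1 -0.26 (SE 0.05) and Tapbp, which encodes tapasin, -0.21 (SE 0.04). The class I heavy chain genes H2-K1 (-0.08, SE 0.04) and H2-D1 (-0.09, SE 0.04) did not pass. For MHC class II, 3 of 10 were lower (3 adjusted over the list alone): Cd74, H2-DMb1 (-0.51, SE 0.12) and Lgmn (-0.21, SE 0.06). These lists passed camera (adjusted p = 2.58e-05 for class I and 0.0066 for class II) and did not with an estimated correlation (adjusted p = 0.0917 and 0.217). Of the 16 components of IFNγ signalling, Stat2 (-0.29, SE 0.06) and Irf1 (-0.17, SE 0.04) were lower, and the list did not pass camera (adjusted p = 0.0594). The receptor gene Ifngr1 (-0.16, SE 0.09) did not pass. Immune checkpoint ligands passed camera as lower (adjusted p = 0.0228; 0.217 with an estimated correlation), with 1 of 10 called, Lgals3 (-0.17, SE 0.04), which encodes galectin-3. Cd274, the gene of PD-L1, had -0.05 (SE 0.11) and did not pass. These genes that did not pass were picked from their lists after their values were seen.

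Cholesterol synthesis genes formed the list with the smallest camera p in the c30 comparison: 14 of 23 were lower and 0 higher (19 lower adjusted over the list alone; camera adjusted p = 1.48e-20, and 0.0364 with an estimated correlation). Insig1, whose product retains the sterol-sensing complex in the endoplasmic reticulum, had -0.48 (SE 0.05) and Mvd, a mevalonate pathway enzyme, -0.52 (SE 0.07). In the hypoxia and glycolysis list, 10 of 24 were lower and 0 higher (15 lower adjusted over the list alone; camera adjusted p = 2.67e-10, and 0.0384 with an estimated correlation). Ndrg1 had -0.59 (SE 0.06) and Pdk1, a kinase that restrains pyruvate oxidation, -0.41 (SE 0.06). Of 22 collagen and matrix genes, 11 were lower and 1 higher (13 and 3 adjusted over the list alone; camera adjusted p = 1.27e-13, and 0.217 with an estimated correlation). Col3a1 went from 311 ± 6.74 CPM to 187 ± 1.86 CPM (SD, n = 2 per group; log2 fold change -0.74, SE 0.05, edgeR adjusted p = 1.30e-21) and Col1a2 had -0.69 (SE 0.05). In the endothelial and stromal marker list 2 of 7 were lower, the growth factor receptor genes Pdgfrb (-0.41, SE 0.07) and Pdgfra (-0.46, SE 0.09), and 2 lower adjusted over the list alone. It passed camera (adjusted p = 0.0325; 0.217 with an estimated correlation). Its summed level was 146 and 155 CPM in the knockdown libraries and 111 and 117 CPM in the c30 libraries. Ribosomal protein genes were higher for 17 of 40 and lower for 0 (24 higher adjusted over the list alone; camera adjusted p = 7.84e-09, and 0.217 with an estimated correlation). Examples were Rplp1 at 0.25 (SE 0.04) and Rps20 at 0.31 (SE 0.05). Many of these genes have near-identical pseudogenes, so their counts are uncertain where the counting could split reads between copies. Higher by camera were also feedback and immediate early genes of the ERK kinase pathway (7 of 20 higher and 2 lower, 7 and 3 adjusted over the list alone; adjusted p = 0.0066, and 0.217 with an estimated correlation), including Ier3 (0.58, SE 0.06) and Dusp6 (0.46, SE 0.07). So were TGF-beta targets (2 higher and 1 lower of 16, 6 and 1 adjusted over the list alone; adjusted p = 0.00096, and 0.143 with an estimated correlation). The called TGF-beta targets included Id1 (0.69, SE 0.08), which BMP signalling also induces, and Tgfbi (-0.49, SE 0.05).

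Other called genes in the c30 comparison lay in lists that did not pass as a whole by camera: integrins and focal adhesion (adjusted p = 0.0561), metalloproteases (0.549), other heparan sulphate proteoglycans (0.204), heparan sulphate synthesis (0.313), epithelial markers (0.0561) and proliferation genes (0.593). They included the integrin genes Itgb4 (-0.51, SE 0.05) and Itga3 (0.27, SE 0.04) and the metalloprotease genes Mmp14 (-0.35, SE 0.06) and Mmp2 (-0.24, SE 0.04). Others were the heparan sulphate proteoglycan gene Gpc1 (-0.38, SE 0.06), the heparanase gene Hpse (-0.88, SE 0.20), Cdh1, which encodes E-cadherin (-0.73, SE 0.17), and the proliferation marker Mki67 (-0.20, SE 0.04). The number of genes that passed was 464 without c30 replicate 1, 485 without c30 replicate 2 and 519 with DESeq2. It was 254 when all 10 libraries were fitted together, of which 25.2% were higher against 42.6% in the MC38 fit.

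The comparison of ect with the knockdown asked the same of the ect form. Cholesterol synthesis genes were lower with ect as a list, also with an estimated correlation. Hypoxia and glycolysis genes, collagen genes, antiviral genes and interferon-induced GTPases were lower and ribosomal protein genes higher by camera with its preset correlation only. With an estimated correlation their adjusted p = 0.0639, 0.172, 0.158, 0.171 and 0.335. Of the genes tested, 1227 genes passed (534 higher and 693 lower of 15031, edgeR adjusted p under 0.05), with a median absolute log2 fold change of 0.29 and with 24 higher and 19 lower genes at least 2-fold apart. Among genes with at least 5 CPM that the rule for named genes takes, the largest rises were in Palld, Cox11 and Id3. Palld, which encodes the actin-associated protein palladin, had 0.96 (SE 0.21), Cox11 0.95 (SE 0.22) and Id3 0.87 (SE 0.08). Next were Tmem171 (0.86, SE 0.24), Id1 (0.78, SE 0.08) and Ost4 (0.71, SE 0.15). Glrx, Dusp5, Rps10 and Ctnnal1 rose by 0.61 to 0.66. The largest falls under the same rule were in Fam180a (-1.53, SE 0.22), Cdh1 (-1.13, SE 0.18) and Col1a1, a chain of type I collagen (-1.04, SE 0.14). Next were Zfp423 (-1.01, SE 0.17), Capn6 (-0.97, SE 0.19) and Ifit3 (-0.93, SE 0.18). Erbb3, Duox1, Tnr and Plin4 fell by 0.87 to 0.91.

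Of the 23 cholesterol synthesis genes, 17 were lower with ect and 0 higher (20 lower adjusted over the list alone; camera adjusted p = 2.19e-32, and 0.0259 with an estimated correlation, the one list of this comparison that held). Mvd went from 93.4 ± 11.2 CPM to 55.1 ± 1.31 CPM (SD, n = 2 per group; log2 fold change -0.76, SE 0.07, edgeR adjusted p = 9.37e-14) and Insig1 had -0.50 (SE 0.05). In the hypoxia and glycolysis list 12 of 24 were lower (12 adjusted over the list alone; camera adjusted p = 2.21e-11, and 0.0639 with an estimated correlation). Ndrg1 had -0.57 (SE 0.06) and the angiogenic factor gene Vegfa -0.41 (SE 0.06). Of 22 collagen and matrix genes 10 were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 3.47e-13, and 0.172 with an estimated correlation), with Col3a1 at -0.71 (SE 0.05). The endothelial and stromal markers included Pdgfrb at -0.46 (SE 0.07) and Pdgfra at -0.57 (SE 0.09) called of 7 (3 lower adjusted over the list alone; camera adjusted p = 0.00565, and 0.171 with an estimated correlation). Their summed level was 112 and 105 CPM. Antiviral interferon-stimulated genes were lower for 7 of 30 (8 adjusted over the list alone; camera adjusted p = 2.20e-05, and 0.158 with an estimated correlation), including Oas3 (-0.45, SE 0.10) and Ifit2 (-0.30, SE 0.08). Of the 17 guanylate-binding and immunity-related GTPases 7 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.00634, and 0.171 with an estimated correlation), with Igtp at -0.31 (SE 0.04) and Iigp1 at -0.25 (SE 0.04). MHC class I genes were lower for 5 of 21 (6 adjusted over the list alone; camera adjusted p = 0.000991, and 0.171 with an estimated correlation), with H2-T23 at -0.40 (SE 0.08), and 0 of 10 class II genes passed. Socs1, which encodes a feedback inhibitor of IFNγ signalling, was higher (0.58, SE 0.12) and Stat2 lower (-0.19, SE 0.06), and the list of signalling components did not pass camera (adjusted p = 0.251). Ccl5, a T cell attracting chemokine, passed at a very low level (0.296 to 1.27 CPM, log2 fold change 2.06, SE 0.69, edgeR adjusted p = 0.0475).

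Ribosomal protein genes were higher with ect for 17 of 40 (20 adjusted over the list alone; camera adjusted p = 4.25e-06, and 0.335 with an estimated correlation). The lists of ERK feedback genes (5 higher and 1 lower of 20, 6 and 1 adjusted over the list alone; camera adjusted p = 9.74e-05), TGF-beta targets (3 higher and 1 lower of 16, 5 and 1 adjusted over the list alone; 0.00565) and YAP targets (2 higher of 15, 3 higher and 1 lower adjusted over the list alone; 0.0403) were higher by camera, with adjusted p = 0.171, 0.171 and 0.207 with an estimated correlation. Those of endoplasmic reticulum chaperones (4 lower of 15, 6 adjusted over the list alone; camera adjusted p = 0.000991), the ATF4 stress response (5 lower of 20, 8 lower and 2 higher adjusted over the list alone; 0.0211) and epithelial markers (2 lower of 5, 2 adjusted over the list alone; 0.0258) were lower, with adjusted p = 0.171, 0.172 and 0.199 with an estimated correlation. Hspa5, which encodes the chaperone BiP, had -0.23 (SE 0.04) and Chac1, an ATF4 target, -0.37 (SE 0.07). Itgb4 (-0.53, SE 0.05), Mmp2 (-0.41, SE 0.04), Gpc1 (-0.47, SE 0.06), Tgfbi (-0.57, SE 0.05) and Mki67 (-0.32, SE 0.04) were lower. The number of genes that passed was 787 without ect replicate 1, 776 without ect replicate 2 and 596 with DESeq2. It was 249 when all 10 libraries were fitted together, of which 26.1% were higher against 43.5% in the MC38 fit.

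The direct comparison of c30 with ect asked where the 2 groups differed. The form of Sdc1 and its counted level differ together between them, so their effects cannot be told apart here. Sdc1 was 2.03 higher on the log2 scale with c30 (SE 0.089, edgeR adjusted p = 5.29e-33). Apart from Sdc1, Egr1, Rps27a and C1s1 were among the genes lower with c30, and Col1a1 and Il1rl1 among those higher. In all, 45 genes passed (20 higher and 25 lower with c30 of 15031, edgeR adjusted p under 0.05; 1310 at an unadjusted p under 0.05). Higher with c30 were Col1a1 (0.83, SE 0.14), Il1rl1, which encodes the receptor of interleukin-33 (0.50, SE 0.08), Gsto1 (0.42, SE 0.09) and the adhesion molecule gene L1cam (0.35, SE 0.06). Frrs1, Zkscan3, Tnnt2, Ctsa, Elovl6 and Spaca6 were 0.22 to 0.33 higher. Lower with c30 were Egr1, an immediate early transcription factor gene (-1.10, SE 0.14), Rps27a (-1.01, SE 0.049), C1s1 (-0.93, SE 0.23), and Prl2c2 (-0.85, SE 0.18). So were Cd74 (-0.79, SE 0.18), C4b, a complement component gene (-0.62, SE 0.12), and Serpina3f (-0.58, SE 0.11). Lower too were the chemokine gene Cxcl10 (-0.52, SE 0.12), Nfkbiz (-0.42, SE 0.09) and Ptgs2, the gene of cyclooxygenase-2 (-0.38, SE 0.07). Of 17 guanylate-binding and immunity-related GTPases 3 were lower and 0 higher (7 lower adjusted over the list alone): Gbp4 (-0.36, SE 0.06), Iigp1 (-0.21, SE 0.04) and Gbp3 (-0.19, SE 0.05). That list passed camera (adjusted p = 2.70e-09), as did antiviral interferon-stimulated genes (lower, 0 of 30 called and 1 adjusted over the list alone; 5.02e-05) and cholesterol synthesis (higher, 1 of 23 called, Fdps, and 2 adjusted over the list alone; 0.00138). Mitochondrially encoded transcripts (higher, 1 of 15 called, mt-Cytb, and 6 adjusted over the list alone) passed as well (camera adjusted p = 0.000264). None of the 4 held with an estimated correlation (adjusted p = 0.175, 0.247, 0.250 and 0.486). The count of genes was 21 without c30 replicate 1, 18 without c30 replicate 2, 15 with DESeq2, 8 with all 10 libraries in one fit, 72 with only the 4 libraries compared and 71 with a correction for transcript length and GC content.

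Because c30 and ect were set against the same knockdown libraries, their overlap was read against simulated groups with no effect. The same direction was found for 666 genes that passed in both comparisons, 265 higher and 401 lower, where independent lists of those sizes would share 17.6 and 30.8. In 40 simulations of unchanged groups against the same controls, 1.1 genes on average and at most 5 passed in both. Across the 10675 genes with a mean of at least 5 CPM in each of both comparisons, which are not independent replicates, the log2 fold changes of c30 and ect had a Pearson correlation of 0.738 and a covariance of 0.0272, where the simulated groups gave 0.488 and 0.00723 (highest covariance 0.00807). Genes called the same way in both included Col3a1, Insig1, Ndrg1, Id1 and Ier3, and 3 genes passed in opposite directions. With the knockdown libraries split, 500 genes were picked by the difference between c30 replicate 1 and knockdown replicate 1. Against knockdown replicate 2, their median log2 shift in the picked direction was 0.262 for ect and 0.326 for c30 replicate 2. The 666 genes were not counted with separate knockdown libraries for each form, so part of that count may come from the shared libraries. A trait common to both knockdown libraries would be absent from the simulations and present in both parts of the split.

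**Figure D2:**
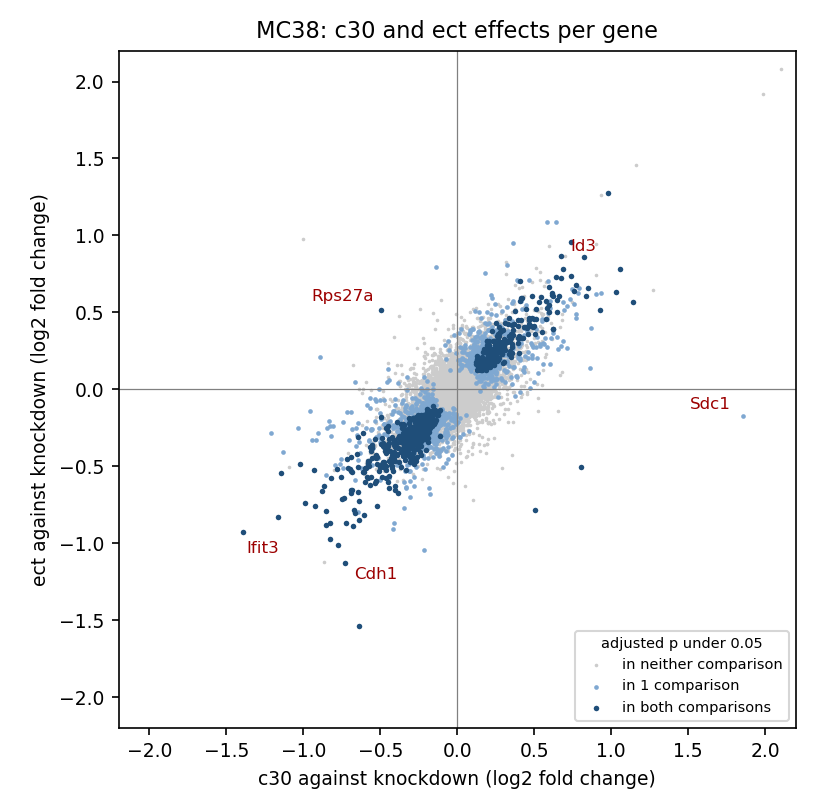
Log2 fold change of each of 10728 genes whose 3 MC38 group means average at least 5 CPM, for c30 against the knockdown (horizontal axis) and ect against the knockdown (vertical axis). Dark points passed the edgeR test in both comparisons (651 genes), light blue points in 1 of them (962 genes) and grey points in neither; Sdc1 lies at 1.86 and -0.17 and Rps27a at -0.49 and 0.51.

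The comparison of wild-type Sdc1 with the knockdown in B16 asked what putting the intact gene back changed in the melanoma line. No gene passed the edgeR test (0 of 14336 at adjusted p under 0.05; 791 at an unadjusted p under 0.05), whereas DESeq2 called 10 genes and limma-voom 0. The edgeR test called 42 genes without the filter on low counts, 27 with all 10 libraries in one fit, 15 with replicate number as a block and 15 with a correction for transcript length and GC content. The smallest p-values among lower genes belonged to Thbs1, which encodes the matrix protein thrombospondin-1 (log2 fold change -0.72, SE 0.09, edgeR adjusted p = 0.101), the complement gene C3 (-0.67, SE 0.10), Col28a1 (-0.63, SE 0.10), Fn1, the gene of fibronectin (-0.50, SE 0.08), and Pde4c (-1.69, SE 0.30). Among higher genes they belonged to Rpl17 (0.87, SE 0.12, edgeR adjusted p = 0.110), Rpl29 (0.46, SE 0.08), Zfp969 (2.03, SE 0.40), Rpl39 (0.55, SE 0.11) and Uqcrh (0.39, SE 0.08). The pseudogene Rpl17-ps10, picked after its value was seen, had -1.03 in the same fit. Whether reads were split differently between it and Rpl17 was not tested. The 2 wild-type libraries differed from each other more than any other pair: the chi-square statistic per degree of freedom between replicates was 20, against 3.79 to 6.27 in the other groups. Part of the 20 comes from the single Ensembl row without a symbol, which took 0.695% of wild-type replicate 1 and 2.42% of replicate 2. In the B16 knockdown that row took 1.42% and 0.65%. The correlation of log2 CPM between replicates was also lowest in the wild-type pair, 0.9916 against 0.9938 to 0.9949. Without wild-type replicate 1 the test called 1295 genes, without wild-type replicate 2 it called 326, without knockdown replicate 1 it called 18 and without knockdown replicate 2 it called 3, where the lone library is assumed to vary like the other group.

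Several gene lists stood apart from all other genes in B16 by camera, with no single member called over all genes. With an estimated correlation 0 of these 14 lists held, with adjusted p = 0.427 for mitochondrial transcripts, 0.595 for the GTPases, 0.641 for ribosomal proteins and 0.347 for the others. Collagen and matrix genes had a median log2 fold change of -0.31 (18 of 20 below 0, 8 lower adjusted over the list alone; camera adjusted p = 5.94e-15). Antiviral interferon-stimulated genes had -0.14 (27 of 30 below 0, 0 adjusted over the list alone; 5.84e-09) and lymphocyte-attracting chemokines -0.16 (8 of 9 below 0, 2 lower adjusted over the list alone; 0.000225). In the chemokine list Cxcl9 had -0.43 (SE 0.08) and Cxcl11 -0.61 (SE 0.12), both picked after their values were seen. Below 0 as well were the ATF4 stress response (median -0.14; 0.000182), and YAP targets (-0.12; 0.0185), each by camera adjusted p. So were guanylate-binding and immunity-related GTPases (-0.03; 0.0206), ligands of natural killer cell receptors (-0.42; 0.0206) and mesenchymal transition genes (-0.13; 0.0248). Above 0 were mitochondrially encoded transcripts (median 0.27; camera adjusted p = 2.34e-08) and cholesterol synthesis (0.13, 22 of 23 above 0, 3 higher adjusted over the list alone; 2.74e-08). Ribosomal proteins (0.10; 0.000421), pigment and melanocyte markers (0.14; 0.00102), proliferation genes (0.06; 0.0206) and endoplasmic reticulum chaperones (0.05; 0.0289) also lay above 0. Mitochondrial transcripts were high in wild-type replicate 2 alone, at 1.78% of its counts against 1.29% to 1.40% in the other B16 libraries. The ATF4 and YAP lists were low mostly in that library, by median log2 ratios to the mean of the other B16 libraries (members at 5 CPM or more). For ATF4 these were 0.02 and -0.17 in wild-type replicates 1 and 2, and 0.06 and 0.14 in the knockdown. For YAP they were -0.01 and -0.11, and 0.04 and 0.11. Over the 5 comparisons, median, mean and test differed in sign for 23 of 147 list tests, of which 0 passed camera. Without wild-type replicate 1 the GTPase and ribosomal protein lists changed direction (camera adjusted p = 0.988 and 0.0768). The lists of IFNγ signalling components, MHC class I, MHC class II and checkpoint ligands did not pass (camera adjusted p = 0.535, 0.112, 0.0572 and 0.662).

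**Figure D3:**
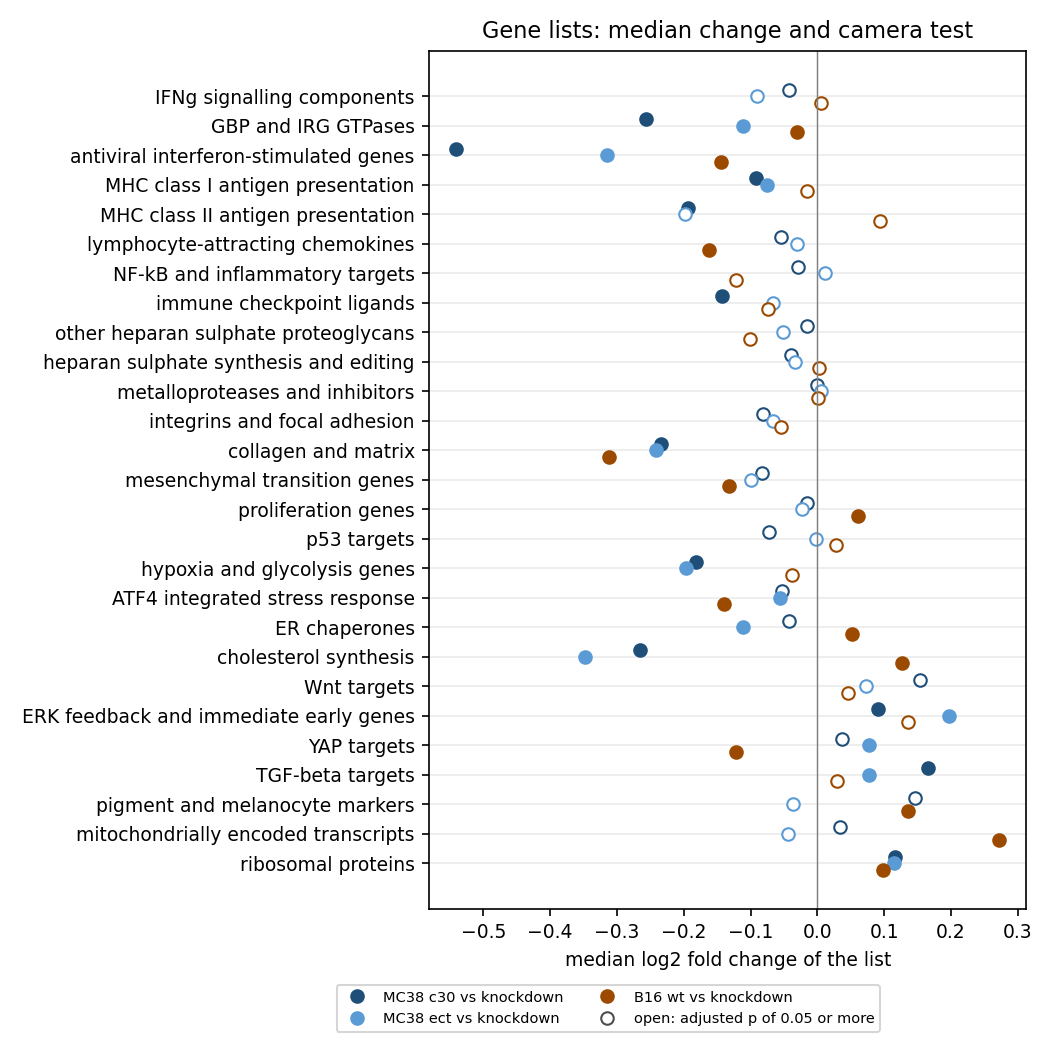
Median log2 fold change (horizontal axis) of the 27 gene lists tested in all 3 comparisons with a knockdown, one row per list. Dark blue points are c30 and light blue points ect against the knockdown in MC38, brown points wild-type Sdc1 against the knockdown in B16; filled points passed camera with the preset correlation (adjusted p under 0.05), open points did not. Cholesterol synthesis lies at -0.27 and -0.35 in MC38 and at 0.13 in B16, and collagen and matrix genes lie below 0 in all 3.

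**Figure D4:**
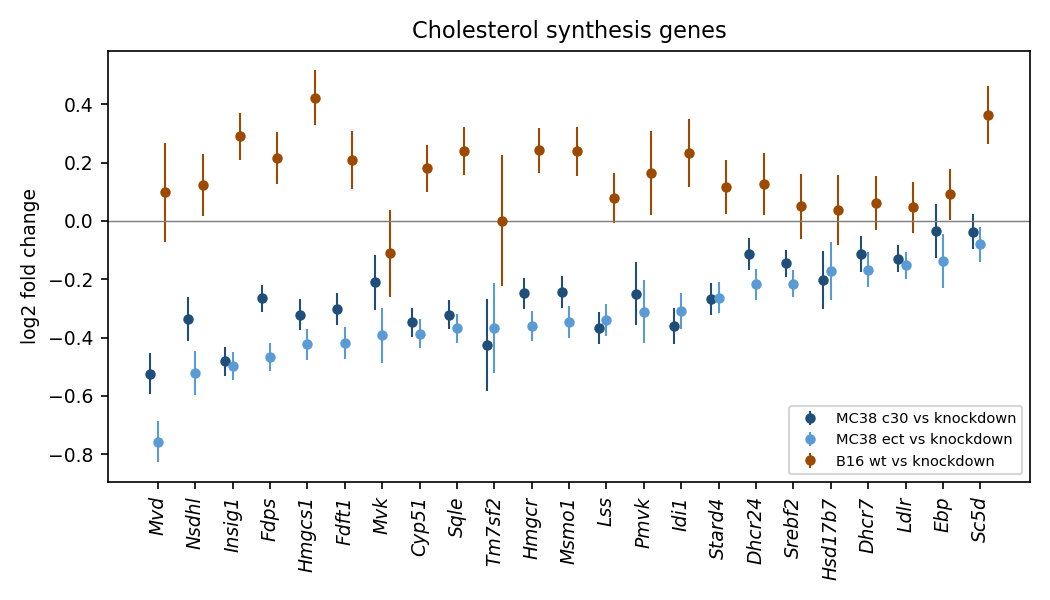
Log2 fold change (vertical axis) of the 23 cholesterol synthesis genes (horizontal axis, ordered by the ect value), with dark blue points for c30 and light blue points for ect against the knockdown in MC38 and brown points for wild-type Sdc1 against the knockdown in B16. Bars are 1 standard error of the edgeR fit; all 23 genes lie below 0 in both MC38 comparisons and 22 lie above 0 in B16.

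The knockdown libraries of B16 and MC38, which had the same treatment, were compared as context on lineage and on the level of interferon-induced genes. Melanocyte genes and antiviral interferon-stimulated genes were higher in B16 as lists. Collagen and mesenchymal transition genes were lower in B16 by camera with its preset correlation and not with an estimated one (adjusted p = 0.215 and 0.136). Both lists passed directional fry (adjusted p = 2.68e-06 and 8.46e-07), but so did 26 of the 31 lists tested, so passing it does not set them apart. Of 16877 genes, 11504 passed (5712 higher and 5792 lower in B16, edgeR adjusted p under 0.05). Dct and Mlana, genes of melanin synthesis and of a melanosome protein, had 0 counts in both MC38 knockdown libraries and were at least 21300-fold and 3760-fold higher in B16, counting 3 counts per library as the floor. The transcription factor gene Sox10 and Vgll3, also at 0 in MC38, were at least 1690-fold and 1340-fold higher, and Tyrp1 was at 4993 CPM in B16 against 0.109 CPM. Dkk2, Slc43a3, Wnt10b, F2rl1 and Slc7a2 had 0 counts in both B16 knockdown libraries and were at least 323-fold, 316-fold, 289-fold, 258-fold and 214-fold lower in B16. All 18 tested pigment and melanocyte markers were higher in B16 (camera adjusted p = 5.69e-22, and 0.00705 with an estimated correlation). Sdc1 itself was 0.66 higher in the B16 knockdown (SE 0.12, edgeR adjusted p = 1.27e-05).

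Antiviral interferon-stimulated genes were higher in B16 than in MC38 for 29 of 30 and lower for 1, with medians of 121 and 11.6 CPM (camera adjusted p = 3.77e-25, and 0.00705 with an estimated correlation). Ifit3 stood at 494 against 12.4 CPM (log2 fold change 5.32, SE 0.09) and Rsad2, which encodes viperin, at 202 against 1.02 CPM. Guanylate-binding and immunity-related GTPases were higher for 14 of 17 and lower for 2 (camera adjusted p = 3.95e-09; 0.136 with an estimated correlation), with Gbp4 at 4.03 (SE 0.08). MHC class II genes were higher for 8 of 10 and lower for 1 (camera adjusted p = 4.28e-05; 0.215 with an estimated correlation), with Cd74 at 239 against 12.9 CPM. The chemokine genes Cxcl10 (5.12, SE 0.08) and Cxcl9 (6.32, SE 0.10) and Cd274 (2.66, SE 0.09) were higher in B16. H2-K1 (-2.09, SE 0.07) and the immunoproteasome gene Psmb8 (-2.30, SE 0.11) were lower. Neither the chemokine list nor the class I list passed (camera adjusted p = 0.128 and 0.342). Lower in B16 as lists were collagen and matrix (17 of 24 lower and 4 higher; 3.24e-07), mesenchymal transition genes (10 of 13; 0.000234), and TGF-beta targets (13 of 17; 3.79e-05). So were NF-kB and inflammatory targets (13 of 21; 0.00036), ERK feedback genes (17 of 21; 0.00036), cholesterol synthesis (20 of 23; 0.000525), YAP targets (11 of 15; 0.00811) and proliferation genes (19 of 32; 0.0136), each by camera adjusted p. None of these 8 held with an estimated correlation (adjusted p of 0.0688 to 0.215). Lgals3 stood at 1.26 CPM in B16 and 783 CPM in MC38, and Itga3 at 0.444 and 445 CPM. Levels differ between lines that also differ in lineage, so the comparison does not bear on Sdc1, and no library without IFNγ is analysed here to give the basal level of these genes.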

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

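The tests of the difference between the B16 and MC38 effects were chosen only after the results were seen.

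In MC38, 3 genes passed in opposite directions with c30 and ect against the knockdown. Rps27a, which encodes a ubiquitin and ribosomal protein fusion, had log2 fold changes of -0.49 with c30 and 0.51 with ect, a difference of -1.01 (edgeR adjusted p = 9.07e-30). The locus XLOC_000041, which has no symbol, differed by 1.31, and Gm8430, a predicted gene, differed by 1.29 between the forms (edgeR adjusted p = 2.56e-05 and 2.18e-07).

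Rps27a stood at 292 and 286 CPM in the knockdown libraries, 192 and 218 CPM with c30 and 412 and 412 CPM with ect (CPM of TMM-normalized library sizes). Gm8430 is one of the 14 genes that share 50-base stretches with Rps27a (372 stretches, with 432 and 409 counts with c30 and 178 and 217 with ect). Part of both opposite changes may therefore come from reads exchanged between them. Reads moving between Rps27a and near-identical copies would leave the family sum level. The summed counts of Rps27a and these 14 genes still differed by -0.766 on the log2 scale. That argues against such moves within the counted family as the whole source. Reads with several matches that were dropped before counting could still contribute, since their handling is not stated. In B16, Rps27a also differed between samples of the same group. The knockdown libraries held 1861 and 2787 of its counts at totals of 13095279 and 11489867, with 436 and 278 counts of Gm8430. The wild-type libraries held 2780 and 2341 Rps27a counts at totals of 12633947 and 12526431. The adjusted p of Rps27a comes from the MC38 libraries alone and does not include that spread. Variation between samples apart from the form of Sdc1 therefore stays open, as does a difference between the forms themselves, which was not tested.

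The effect of wild-type Sdc1 in B16 differed from that of c30 in MC38 for 48 genes (25 higher and 23 lower in B16) and from that of ect for 82 genes (48 higher and 34 lower), by an edgeR test of the difference over all 10 libraries. The cholesterol synthesis list had a median difference of 0.444 on the log2 scale against c30 (10 of 23 genes called; camera adjusted p = 8.29e-31, and 0.00144 with an estimated correlation). Against ect the median difference was 0.476 (12 of 23 called; camera adjusted p = 3.21e-40, and 0.000743 with an estimated correlation). Insig1 had a log2 fold change of 0.29 in B16 and of -0.48 and -0.50 with c30 and ect, and Hmgcs1, picked after its values were seen, had 0.42, -0.32 and -0.42. Without wild-type replicate 1 the list's median difference was 0.420 and 0.521 (adjusted p = 0.0197 and 0.0124 with an estimated correlation), and without wild-type replicate 2 it was 0.441 and 0.484 (0.00694 and 0.00488). The lines differ in lineage and in the form of Sdc1 at once, so these cannot be separated by this design.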

How the results depend on the processing

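The tests chosen only after the results were seen were the correction for transcript length and GC content, the fit without unnamed loci, and the list tests without single libraries. For the number of genes called, 36 settings other than leaving out a library gave a count within 1.5 times the reported one and 17 did not. DESeq2 called 519 genes for c30, 596 for ect, 15 for c30 against ect and 10 in B16. All 10 libraries in one fit called 254, 249, 8 and 27. A fold change of at least 2 left 60, 43 and 7 genes in MC38, 6271 between the lines, and 9 of the 666 genes shared by c30 and ect. For c30 against ect, only the 4 libraries compared gave 72 and the length and GC correction 71. In B16 that correction gave 15, no filter 42 and replicate number as a block 15. Replicate deviations paired by number had correlations of 0.0641, -0.00894 and 0.0211 in MC38 and -0.184 in B16. These were at most weakly positive, which leaves open whether samples of the same number were paired. Leaving out a library gave 464 to 992 genes for c30, 776 to 984 for ect, 18 to 44 for c30 against ect and 3 to 1295 in B16, where the lone library is assumed to vary like the other groups. Lists called numbered 4, 1, 0, 0 and 2 with an estimated correlation (c30, ect, c30 against ect, B16, between lines) and 27, 28, 15, 8 and 30 with fry for a change in either direction. Directional fry called 12 lists for c30, 12 for ect, 3 for c30 against ect, 1 in B16 and 26 between lines. Without wild-type replicate 1, the guanylate-binding and immunity-related GTPases and ribosomal proteins in B16 reversed; leaving out a library gave adjusted p from 1.86e-07 to 0.988 and from 2.93e-28 to 0.0768. Of the named genes' values under settings other than leaving out a library, 1562 kept direction and side of the threshold, 135 were weaker and 29 stronger. All of the stronger ones were in B16 wild-type against the knockdown. Between the lines, all 76 named genes stayed the same in each such setting. In c30 against ect, 17 were weaker and 10 the same with DESeq2. With all 10 libraries in one fit 21 were weaker and 6 the same, and with RLE all 27 stayed the same. Except where fewer libraries or a stricter threshold shows it, the cause was not tested. In simulated counts 1.2-fold changes were recovered for 24% of genes at most, so changes of that size are largely missed at this depth and number of libraries.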

Other observations

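The tests with a correction for transcript length and GC content, and those of the size of the B16 shift and of cholesterol synthesis genes in B16, were chosen only after results were seen, as were Xdh, Klf4, Msln, Sdc2 and Thbs1 as examples.

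Several genes not described above were lower with both forms in MC38 by the edgeR test. Xdh, which encodes xanthine dehydrogenase, had log2 fold changes of -0.58 with c30 and -0.47 with ect (adjusted p = 3.52e-16 and 1.81e-12). Klf4, a transcription factor gene, had -0.53 and -0.43 (5.82e-15 and 2.78e-11), and Msln, the gene of mesothelin, -0.49 and -0.32 (1.72e-11 and 4.48e-06). Sdc2, another syndecan gene, had -0.24 and -0.31 (0.0485 and 0.00377). Thbs1, which had the smallest p among lower genes in B16, had -0.56 with c30 in MC38 (adjusted p = 0.00154) and -0.26 with ect (0.194).

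The 666 genes that c30 and ect moved the same way in MC38 were weighed against several explanations. Over the 10675 genes at 5 CPM or more, the covariance of both sets of log2 fold changes was 0.0272. It lay above the highest of the simulated unchanged groups, 0.00807. That argues against the spread between single knockdown samples as the whole source. The simulated spread was that between the 2 samples of a group, so a trait common to both knockdown libraries was not in it and stays open. After the length and GC correction, 92.8% of the 666 genes (618) stayed called in both, which argues against length and GC bias. On 500 genes picked by c30 replicate 1 against knockdown replicate 1, the median shift of ect against knockdown replicate 2 was 0.804 of that of c30 replicate 2 (95% bootstrap interval 0.706 to 0.904) although its Sdc1 count was not above the knockdown, but ect transcripts may be counted incompletely under Sdc1, so the count does not give their level and the prediction that rested on it decides nothing. In B16, 306 of the 589 genes tested moved the same way, with a signed median of 0.00718 (random range -0.0142 to 0.0103). That was 0.0255 of the signed median in MC38 (95% bootstrap interval over genes, which are not independent, -0.0280 to 0.0853). The genes were picked because they passed in MC38, which can raise the MC38 median and lower the ratio. The interval does not allow for that. The cholesterol synthesis list differed by 0.444 from c30 towards higher levels. Collagen and matrix genes, picked after their values were seen, were lower in B16 (median -0.31) as with c30 (-0.23) and ect (-0.24). The signed median argues against wild-type Sdc1, at its level in B16, moving the 589 genes as a set by as much as in MC38. The cholesterol difference argues against its lowering those genes there. A much smaller shift is undecided. Sdc1 rose less in B16 (log2 fold change 0.64) than with c30 (1.86), and no B16 library with c30 or ect is analysed here. An effect of putting a construct into MC38 cells, whatever its Sdc1 content, may also account for the 666 shared genes. It could not be tested without a vector-only group.

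Wild-type replicate 2 stood apart from the other B16 libraries. Removing each library's trend on transcript length and GC content took away 73.8% of the excess spread of its log2 ratios (SD 0.22 before and 0.172 after), and its ratios had a Spearman correlation of -0.68 with GC content across genes, which are not independent replicates. Such a bias is a candidate explanation for the spread in B16, and no biological explanation was tested.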
